A study of Mus musculus with 4 samples.

How the data were processed

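Gene expression was measured by RNA sequencing of splenic CD4+ T cells from B6 mice aged 6 weeks, stimulated with phorbol ester (PMA) and the calcium ionophore ionomycin. Each of 4 genotypes gave 1 library: wild type, Itch knockout (a floxed Itch allele deleted by Cd4cre), WWP2 knockout, and a library labelled as the double knockout of Itch and WWP2. Per the labels' protocols, RNA was extracted with a column kit and libraries were made after mRNA enrichment. How long the cells were stimulated and how many mice stood behind a library are not given in the sources used here.

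The values analysed were raw counts of reads per gene, deposited by the authors in 1 table of 21937 gene symbols by 4 libraries, with no normalization. Bowtie 1.0.0, TopHat 1.4.1, HTSeq 0.7.1 and the mouse build mm9 are named in the submitters' processing notes. The gene annotation, the strand setting, the read length and any filter are not given in the sources used here. A gene and its antisense partner, or near-identical members of a gene family, can therefore share or lose reads. The table held no rows of unassigned reads, and 6483 genes had no read in any library. It gave no coordinates, and since the reference supplied was of another build (GRCm38), none are printed. The RefSeq gene table of GRCm38.p6 served only to tell which genes neighbour Wwp2 and how many chromosomes hold a set of genes; 99.0% of the table's symbols matched it by name or synonym.

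Counts were scaled by trimmed mean of M values (TMM) factors from all 4 libraries with edgeR 4.0.16 in R 4.3.3. The factors were 0.984 for wild type, 0.983 for Itch KO, 1.00 for WWP2 KO and 1.03 for the library labelled double KO. Ratios are of TMM-scaled counts (CPM, counts scaled to a common library size), given as folds without a prior count, or on the log2 scale with a prior count of 2, which draws the ratios of low counts towards 0. With 1 library per genotype there is no spread between replicates, and no p-value was computed across genes for any comparison of single libraries. A size rule was used in its place. A gene was called at least 2-fold higher or lower when its log2 ratio reached 1 in either direction, its mean over the 4 libraries was at least 2 CPM (9926 genes), and the exact conditional binomial 95% interval of the fold excluded 1. These intervals, and the exact Poisson 95% intervals of single levels, cover counting error only. Reads without molecular identifiers are not independent molecules, and such a call compares 2 libraries, not 2 genotypes. A fold against a count of 0 is a lower bound, computed against 3 counts in that library.

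Effects of each ligase were also compared between pairs that share no library, by Pearson and Spearman correlation across genes, which are not independent replicates. For the single knockouts, which share the wild-type library, unchanged groups were simulated 20 times at each of 3 dispersions. An additive model with terms for Itch loss and WWP2 loss was fitted with edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment and a threshold of 0.05. It leaves 1 residual degree of freedom, so the departure from additivity serves as its only spread between libraries, and a response to the joint loss alone is divided between the terms and the residual. Computation outside R used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

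Before the data were examined, 41 gene lists were written down, 28 of function, 12 of other cell types and 1 of sex-linked genes. For each list the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins; the percentile describes these libraries. Genes named in the text were fixed by a rule: Itch and Wwp2; the 12 highest and 12 lowest ratios past the size rule in the library labelled double KO against wild type; the 10 highest and 10 lowest in each single knockout; the 6 farthest above and below all other libraries in the library labelled double KO; 16 cytokine and lineage genes whatever their values; up to 2 highest and 2 lowest members of a described list; and for the additive model the 5 smallest p-values per direction. Unnamed gene models, small RNAs, antigen receptor segments and sex-linked genes were left out of the rankings. Any gene outside the rule is said to be chosen after its values were seen. A few genes that the rule or the lists name are not reported here.

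The size rule was tested on simulated counts for the library labelled double KO against wild type, with 200 genes changed. Over 9932 genes at a dispersion of 0.05 it recovered 42.0% of genes changed 2-fold, 90.0% of those changed 3-fold and 98.0% of those changed 4-fold, with 346 false calls. At a dispersion of 0.01 (9925 genes) and with Poisson noise (9928 genes) there were 0 false calls. The additive model, simulated for Itch loss over 11293 genes at a dispersion of 0.05, recovered 23.0% of 2-fold and 96.0% of 4-fold changes with 5 false calls.

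The alternatives tried were plain library totals, DESeq2 1.42.0 size factors, no low filter, a minimum of 10 CPM, a prior count of 0.5, a 99.9% interval, counts thinned to the smallest library, a ratio of 1.5, and the removal of receptor segments, sex-linked genes and markers of other cells. The additive model was also run with DESeq2's Wald test, limma-voom (limma 3.58.1), DESeq2 size factors and no low filter. List medians were replaced by means, and random lists were drawn without matching. Scaling and filtering without the library labelled double KO was added after seeing the data.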

Results

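The data were read counts per gene from 4 RNA sequencing libraries of mouse splenic CD4+ T cells activated with PMA and ionomycin, a pair of drugs that triggers protein kinase C and calcium signalling downstream of the T cell receptor. The genotypes were chosen to ask what Itch and WWP2, ubiquitin ligases of the NEDD4 family, do in T cell activation, alone and together. There was 1 library each for wild type, Itch KO, WWP2 KO and the combination, so none of the differences between single libraries has a replicate check. Total counts were 17627531 in wild type, 17640778 in Itch KO, 17130747 in WWP2 KO and 17990392 in the library labelled double KO. The 10 most abundant genes took between 6.23% and 7.13% of the reads. Depth therefore limited the 4 libraries alike.

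The targeted genes were examined first. Wwp2 had 1363 reads in wild type, 1332 in Itch KO and 4 in WWP2 KO, a level 337-fold lower than wild type in the last (95% counting interval 131 to 1238). The library labelled double KO had 1135 Wwp2 reads, or 0.777 of the wild-type level (0.717 to 0.841). This puts its label in doubt, and it is called the library labelled double KO throughout. Itch had 2083 reads in wild type, 1914 in Itch KO, 1996 in WWP2 KO and 2389 in the library labelled double KO. A count over the whole gene includes exons outside a deleted part, so the Itch counts check neither of the Itch labels. Male-specific genes were read in every library (Ddx3y 4428, 4511, 4189 and 4743 reads, in the order above), with 0, 2, 1 and 4 reads of Xist.

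**Figure D1:**
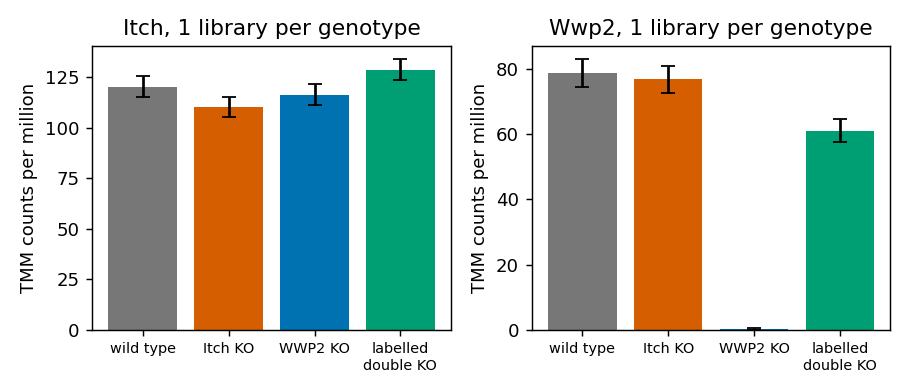
TMM-scaled CPM of Itch (left) and Wwp2 (right) in each of the 4 libraries, with exact Poisson 95% intervals that cover counting error only. Wwp2 was close to 0 in the WWP2 KO library, with 4 reads, and had 1135 reads in the library labelled double KO.

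The Itch KO library was compared with wild type to see what loss of Itch does in stimulated cells. Genes of type 2 helper cells were among the highest. Il5, which encodes the eosinophil growth factor IL-5, was 208-fold higher (116 to 417), with 11 reads in wild type and 2290 in Itch KO. Il13 was 27.4-fold higher (22.8 to 33.2) and Il4 was 8.74-fold higher (5.85 to 13.5). Il9 had 1 read in wild type and 406 in Itch KO, and Il6 had 1 and 57. Gata3, the lineage factor of type 2 cells, was 4.53-fold higher (4.15 to 4.95) and Il10 was 4.42-fold higher (3.56 to 5.52). The 10 highest ratios took in Il5, Il13, Il9 and Il6, but not Il4, Gata3 or Il10. Others among them were Hdc, the enzyme that makes histamine, at 22.8-fold (14.4 to 38.2), the chemokine gene Cxcl3 at 22.8-fold (13.6 to 41.2) and the granzyme gene Gzma at 20.3-fold (12.5 to 35.2). The rest were the leukotriene receptor gene Cysltr1 at 17.8-fold (13.1 to 24.7), the IL-1 receptor antagonist gene Il1rn at 21.5-fold (8.10 to 80.7) and Rnf152, with 2 reads in wild type and 87 in Itch KO.

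In all, 485 genes were at least 2-fold higher and 84 at least 2-fold lower in Itch KO than in wild type. The lowest was Slc15a2, a peptide transporter gene, with 506 reads in wild type and 5 in Itch KO, 101-fold lower (43.1 to 313). It had 493 reads in WWP2 KO and 490 in the library labelled double KO. St8sia1 was 4.67-fold lower (4.03 to 5.43), Eps8l1 4.66-fold (3.72 to 5.89), the adhesion gene Amigo2 4.11-fold (3.50 to 4.85) and Dapl1 3.68-fold (2.40 to 5.81). Ncf1, a subunit of the NADPH oxidase, was 3.53-fold lower (3.12 to 4.01), the pro-apoptotic gene Bbc3 3.50-fold (2.91 to 4.23), the interferon-induced gene Ifit3 3.47-fold (2.64 to 4.62), the pattern receptor gene Tlr6 3.47-fold (2.32 to 5.32) and the growth factor gene Pdgfb 3.40-fold (3.04 to 3.82). Ptpn6, which encodes the phosphatase SHP-1, was 2.04-fold lower (1.90 to 2.19). Il2 was 1.12-fold the wild-type level (1.08 to 1.17), Tnf was 0.941-fold (0.909 to 0.974) and Ifng, from 312 to 469 reads, had a log2 ratio of 0.58, none past the 2-fold rule. Csf2 was 2.78-fold higher (2.26 to 3.46), Il21 was 3.22-fold higher (2.55 to 4.08) and Il3 was 6.81-fold higher (4.01 to 12.3). Tbx21 was 1.15-fold (1.08 to 1.21) and Foxp3 1.67-fold (1.60 to 1.75). Il17a had 0 reads in wild type and 5 in Itch KO, too few for a statement.

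Grouped by the lists, 15 of 17 measured TH2 genes were at least 2-fold higher in Itch KO and 0 were lower, with a median log2 ratio of 1.95 (percentile 100 of the matched random lists). The other members were Il4ra, at 0.56, and Stat6, at -0.15. Effector and memory genes followed, 16 of 26 higher and 0 lower with a median of 1.41 (percentile 100), led by the galectin genes Lgals3 at 2.84 and Lgals1 at 2.19. Among cell cycle genes 20 of 37 were higher and 0 lower, median 1.17 (percentile 100), with the mitotic kinase gene Aurkb at 2.44 and the spindle gene Tpx2 at 2.32. At the other end were Cdk4 at -0.23 and Ccnd3 at -0.80. Treg genes were higher in 9 of 18 cases and lower in 0, median 1.02 (percentile 100), led by the integrin gene Itgae at 2.38 and Il10 at 2.12. Adhesion and chemokine receptor genes were higher in 12 of 27 cases and lower in 1, median 0.89 (percentile 100), with Itga2 at 3.38 and Ccr1 at 2.55.

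Of the cytokine and chemokine genes, 13 of 30 were higher in Itch KO and 1, Il16, was lower at -1.01, with a list median of 0.75 (percentile 100). Coinhibitory and TNF receptor family genes were higher in 7 of 17 cases and lower in 0, median 0.67 (percentile 100), led by Havcr2 at 3.38 and Lag3 at 2.21. TH1 genes were higher in 4 of 13 cases and lower in 0, median 0.60 (percentile 100), led by Eomes at 1.61 and Ccl5 at 1.56. Immediate early genes, which respond first to stimulation, were higher in 3 of 31 cases and lower in 0, median 0.55 (percentile 100), with Atf3 at 1.26 and Fosb at 1.19. TFH genes were higher in 4 of 13 cases and lower in 1, median 0.31, with Il21 at 1.67 and Tcf7 at -1.27. TH17 genes were higher in 3 of 7 cases and lower in 0, median 0.79, with Il21 and the receptor gene Ahr, at 1.54, leading. Naive and quiescence genes were lower in 3 of 22 cases, Dapl1 (-1.81) farthest, with a median of -0.02 at percentile 43.6 and a mean of -0.18 at percentile 0.720. T cell receptor signalling components had 0 of 31 genes past the rule in either direction, from 0.69 for Cd247 to -0.53 for Cd28. A minimum of 10 CPM gave 233 genes higher and 45 lower, and no low filter gave 183 lower.

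**Figure D2:**
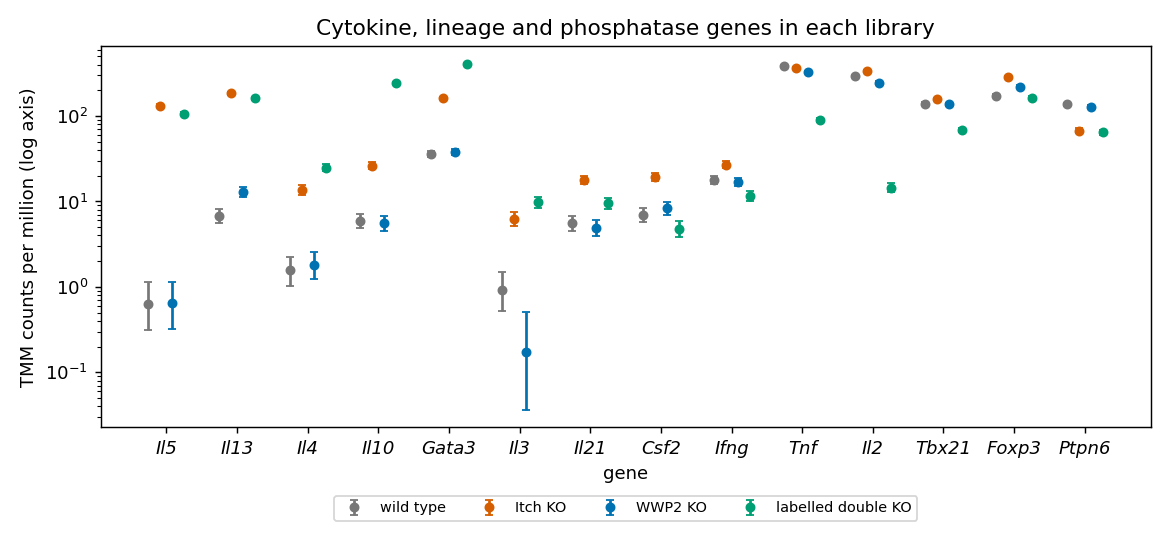
TMM-scaled CPM on a log axis for cytokine, lineage and phosphatase genes in each of the 4 libraries, 1 point per library with its exact Poisson 95% interval. Il5, Il13, Il4 and Il10 were higher in Itch KO and in the library labelled double KO than in the others, while Il2 and Tnf were lowest in the library labelled double KO.

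The WWP2 KO library, set against wild type to ask what loss of WWP2 alone does, differed far less. There were 28 genes at least 2-fold higher and 16 at least 2-fold lower, Wwp2 itself among the latter. The simulated size rule gave 346 false calls at a dispersion of 0.05 and 0 at 0.01, for another pair of libraries. The dispersion of these libraries is not known, so this number of calls does not by itself show an effect of WWP2 loss. Klk1b22, a kallikrein gene, had 0 reads in wild type and 115 in WWP2 KO, at least 38.8-fold higher; it belongs to a family of near-identical copies, so the assignment of its reads is uncertain. Mid1, which encodes a ubiquitin ligase of microtubules, was 29.2-fold higher (23.6 to 36.5), from 89 to 2570 reads. Pstpip2 was 13.4-fold higher (8.38 to 22.6), Setbp1 4.26-fold (3.33 to 5.52), Cdc42bpb 3.68-fold (2.01 to 7.21), Pydc3 3.10-fold (2.72 to 3.54), Mctp1 2.84-fold (1.70 to 4.92) and Msi2 2.74-fold (2.53 to 2.97). Ppic was 2.67-fold higher (1.71 to 4.29) and Arrdc4, an adaptor of NEDD4-family ligases, was 2.65-fold higher (1.80 to 3.98).

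On the other side, the metallothionein genes Mt1 and Mt2 were 6.59-fold (2.78 to 19.0) and 3.46-fold (1.54 to 8.79) lower in WWP2 KO than in wild type. Il3 was 5.27-fold lower (1.51 to 28.2) on 16 and 3 reads. Phlda3 was 3.65-fold lower (2.62 to 5.18), Pttg1 3.39-fold (2.55 to 4.56), Efr3b 3.05-fold (1.92 to 4.99), Fgfbp3 2.70-fold (1.70 to 4.41) and Cdk5rap1 2.65-fold (2.16 to 3.26). Cdk5rap1 stood at 348 reads in wild type and at 125, 130 and 137 in the other libraries. Rpph1, an RNA without a poly(A) tail, was 2.97-fold lower (1.46 to 6.51), and Oaz1 was 2.60-fold lower (1.43 to 4.95). Il5 was 1.01-fold the wild-type level (0.398 to 2.57), Il4 1.16-fold (0.671 to 2.02), Il13 1.89-fold (1.51 to 2.39), Gata3 1.07-fold (0.953 to 1.19), Il10 0.933-fold (0.698 to 1.24), Il2 0.832-fold (0.798 to 0.866) and Ptpn6 0.936-fold (0.883 to 0.993). None of these genes passed the rule.

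Few members of the lists passed the rule in WWP2 KO. There were 0 of 17 TH2 genes, 0 of 26 effector and memory genes, 0 of 37 cell cycle genes and 0 of 31 immediate early genes, with medians of 0.10, -0.09, -0.03 and 0.03 (percentiles 99.4, 1.14, 18.9 and 98.5). The cell cycle mean was -0.09 (percentile 0.780). Il3 was the only cytokine or chemokine gene of 30 to pass, and Klrg1, at -1.02, the only Treg gene of 18. The Treg median was 0.23 and the naive and quiescence median 0.21, each at percentile 100 of the matched lists with 0 genes at least 2-fold higher. Medians low among their matched lists were those of unfolded protein and integrated stress response genes (-0.15) and oxidative phosphorylation genes (-0.11), both at percentile 0, ribosomal protein genes (-0.13, 1 of 10000 matched lists at or below) and heat shock genes (-0.13, percentile 0.570), with 0 genes past the rule. Low medians of ribosomal protein genes (-0.18, percentile 0) and oxidative phosphorylation genes (-0.11, percentile 0.590) were also found in Itch KO against the same wild-type library. They were therefore not particular to WWP2 KO. The stress response (0.03, percentile 80.5) and heat shock (-0.01, percentile 57.6) medians were not low in Itch KO. Without a low filter the counts were 117 higher and 56 lower, and with a minimum of 10 CPM they were 6 and 7.

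The library labelled double KO was compared with wild type to see the effect of losing both ligases; since it held Wwp2 reads, the direction of each difference here belongs to the library and not to a known genotype. It had 1220 genes at least 2-fold higher and 629 at least 2-fold lower. Hdc was 547-fold higher (350 to 909), with 11148 reads against 19. Gzma was 167-fold higher (104 to 287), Il5 169-fold (94.1 to 339), the chemokine receptor gene Ccr1 184-fold (78.7 to 569) and the synaptic vesicle gene Sv2c 225-fold (109 to 560). Genes with 0 reads in wild type were Efna5, an ephrin gene, at least 346-fold higher, Klk1b22, at least 158-fold, Adamtsl3, at least 102-fold, and the lipid transfer gene Pltp, at least 75.3-fold. Il6 had 1 read in wild type and 641 in this library, Fam20a had 1 and 381, and Rnf152 had 2 and 485. Il13 was 23.9-fold higher (19.9 to 29.0), Il4 15.9-fold (10.8 to 24.4), Il10 41.0-fold (33.7 to 50.3), Gata3 11.3-fold (10.4 to 12.3) and Il3 10.6-fold (6.36 to 19.0).

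Among the fixed cytokine genes, Il2 and Tnf passed the rule as lower in that library. Il2, the T cell growth factor gene, was 20.4-fold lower, with 5139 reads in wild type and 270 in the library labelled double KO. Tnf was 4.27-fold lower (4.05 to 4.51) and Tbx21, the lineage factor gene of type 1 cells, was 2.04-fold lower (1.91 to 2.19). Ifng was at 0.646-fold (0.540 to 0.771), Csf2 at 0.686-fold (0.516 to 0.910), Il21 at 1.70-fold (1.32 to 2.20) and Foxp3 at 0.943-fold (0.897 to 0.993), none past the rule. Il17a had 0 and 8 reads. Ptpn6 was 2.14-fold lower, with 2391 and 1196 reads. The lowest ratio was that of the cystine transporter gene Slc7a11, 31.1-fold lower (14.8 to 78.3). Amigo2 was 22.0-fold lower (15.8 to 31.5), Ncf1 21.4-fold (16.4 to 28.4), Arhgap29 15.0-fold (9.42 to 25.3), Nrn1 14.6-fold (9.85 to 22.4) and Pdgfb 12.8-fold (10.5 to 15.6). Ifit3 was 11.5-fold lower (7.42 to 18.7), Itm2a 11.3-fold (10.5 to 12.1), Ttc28 10.2-fold (8.78 to 11.9) and the carbonic anhydrase gene Car2 10.1-fold (8.23 to 12.5).

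By list, 16 of 17 TH2 genes were at least 2-fold higher in the library labelled double KO than in wild type and 0 were lower, median 3.50 (percentile 100), with Stat6, at -0.69, the member that did not pass. Effector and memory genes were higher in 19 of 26 cases and lower in 0, median 2.50 (percentile 100), with Lgals3 at 6.60 and S100a6 at 5.01. Cell cycle genes were higher in 24 of 37 cases and lower in 1, median 2.49 (percentile 100), with E2f2 at 4.08, Aurkb at 4.06, Ccnd2 at -0.97 and Cdk4 at -1.37. Adhesion and chemokine receptor genes were higher in 13 of 27 cases and lower in 3, median 0.97, from Ccr1 at 7.05 to the lymph node homing receptor gene Ccr7 at -2.05. Treg genes were higher in 8 of 18 cases and lower in 0, median 0.93, with Entpd1 at 5.65, Il10 at 5.33 and Foxp3 at -0.08. Coinhibitory and TNF receptor family genes were higher in 7 of 17 cases and lower in 2, median 0.22 and mean 0.95, with Havcr2 at 6.26, Lag3 at 4.97 and Btla at -1.38.

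Ribosome biogenesis genes were lower in 11 of 28 cases in the library labelled double KO and higher in 0, median -0.91 (percentile 0), from Bop1 at -0.32 to Utp20, 2.82-fold lower (2.70 to 2.96). Naive and quiescence genes were lower in 8 of 22 cases and higher in 2, median -0.59 (10 of the 10000 matched lists at or below it), with Il7r at 2.37 and Tcf7 at -2.41. TH1 genes were lower in 5 of 13 cases and higher in 1, median -0.48 (percentile 1.11; mean -0.30, percentile 4.60), from Il18rap at 2.39 to Lta at -1.92. NF-kB target genes were lower in 3 of 25 cases and higher in 1, median -0.36 (percentile 7.96), from Bcl3 at 2.55 to Tnf at -2.09. Immediate early genes were higher in 8 of 31 cases and lower in 3, median 0.51 (percentile 100), with Ier3 at 3.06, Jun at 1.84, Dusp2 at -1.15 and Cd69 at -1.34. Cytokine and chemokine genes split, 10 of 30 higher and 10 lower; their median was -0.32 and their mean 0.68, of opposite sign. TFH genes were higher in 3 of 13 cases and lower in 3, with a median of -0.52 and a mean of 0.01. TH17 genes were higher in 3 of 7 cases and lower in 2, from the IL-1 receptor gene Il1r1 at 6.02 to Il22 at -2.32. T cell receptor signalling components were higher in 3 of 31 cases and lower in 1, median 0.09, from Cd3g at 1.13 to Cd5 at -1.24. Without a low filter 1924 genes were higher, and with a minimum of 10 CPM 666 were.

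**Figure D3:**
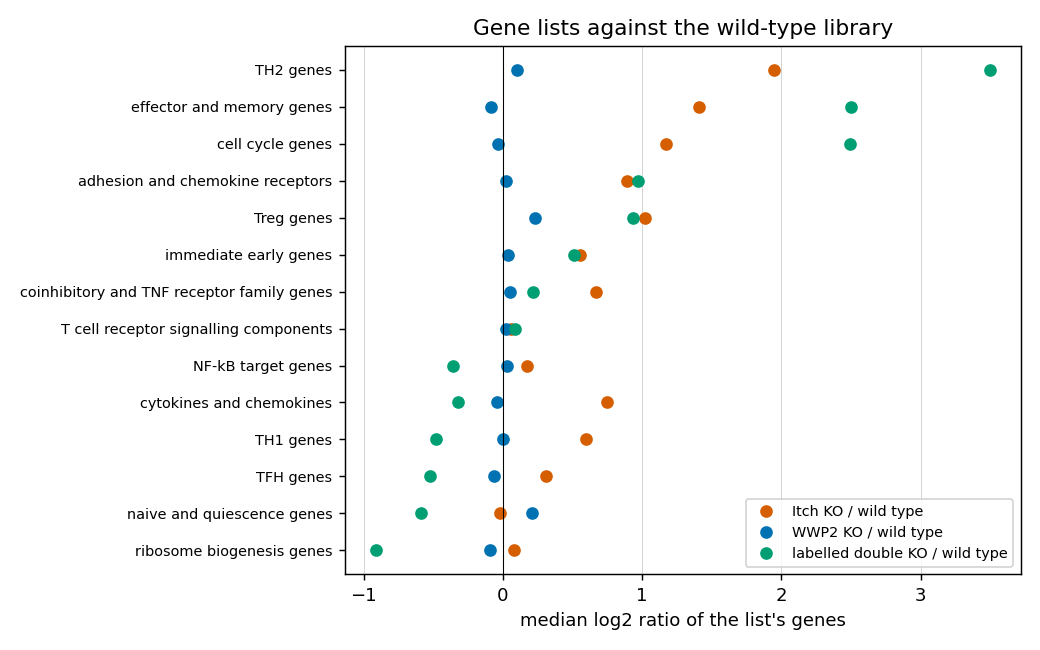
Median log2 ratio of 14 gene lists in Itch KO, WWP2 KO and the library labelled double KO, each against the wild-type library, 1 library per genotype. TH2, effector and cell cycle lists lay highest in the library labelled double KO, with medians of 3.50, 2.50 and 2.49, and the ribosome biogenesis list lowest, at -0.91; the cytokine and TFH medians of that library have means of the opposite sign.

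Next came the question of what the library labelled double KO showed beyond either single knockout. Against Itch KO it had 911 genes at least 2-fold higher and 512 lower, and against WWP2 KO 1155 higher and 601 lower. It lay at least 2-fold above each of the other 3 libraries for 749 genes and below each of them for 336. The same counts were 1 and 12 for wild type, 21 and 8 for Itch KO, and 3 and 11 for WWP2 KO. Farthest above were Efna5, with 1113 reads against at most 17 elsewhere, Adamtsl3, with 327 against at most 4, Ifi27l2b, with 189 against 0, Gfra2, with 332 against at most 4, Akap6, with 257 against at most 3, and B3galt2, with 268 against at most 4. Farthest below were Il2, at a log2 ratio of -4.07 to WWP2 KO, Slc7a11, 9.34-fold (4.27 to 24.2) under Itch KO, and Car2, 7.98-fold (6.49 to 9.90) under Itch KO, each set against its nearest library. They were followed by Zbtb16, the gene of the transcription factor PLZF, 7.42-fold (5.31 to 10.6), and Adamts6, 7.18-fold (5.55 to 9.43), both under wild type.

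Type 2 genes did not all stand higher in the library labelled double KO than in Itch KO. Il10 was 9.28-fold higher (8.42 to 10.2), Hdc 24.0-fold (21.8 to 26.5) and Gata3 2.50-fold (2.39 to 2.61), while Il4, at 1.82-fold (1.55 to 2.14), Il5, at 0.811-fold (0.763 to 0.862), and Il13, at 0.872-fold (0.830 to 0.917), did not reach 2-fold. Il9 was 10.6-fold lower (7.68 to 15.0), Csf2 4.06-fold lower (3.20 to 5.18), Ifng 2.33-fold lower (1.98 to 2.75) and Tnf 4.02-fold lower (3.80 to 4.24). Of the TH2 genes 9 of 17 were higher and 1 was lower, and of the cytokine and chemokine genes 4 of 30 were higher and 16 lower (median -1.23). Set against the sum of the single differences on the log2 scale, 876 genes were 1 or more above it and 525 were 1 or more below, a count with no test, since the 4 libraries leave no residual. The genotype of this library is in doubt, so these counts describe how far it lay from the others.

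To see whether loss of Itch went with the same genes in both WWP2 backgrounds, Itch KO over wild type was set against the library labelled double KO over WWP2 KO, pairs that share no library. Across genes the correlation was 0.70 (Pearson) and 0.45 (Spearman). In both pairs 425 genes were at least 2-fold higher, where independent lists would share 56.4, and 58 were lower, where 5.09 would be shared; 2 genes went opposite ways. Of the genes higher in Itch KO 87.6% were higher in the other pair too. The 425 genes had a median log2 ratio of 1.59 in the first pair and 3.02 in the second, and 302 of them were at least 2-fold higher in the library labelled double KO than in Itch KO. Il5, Il13, Il4, Gata3, Il10 and Hdc were higher in both pairs, and Ptpn6 was 2.04-fold (1.90 to 2.19) and 2.01-fold (1.87 to 2.15) lower. The Wwp2 reads leave the background of the second pair uncertain. The label of the library labelled double KO states no Itch allele, so the Itch loss of the 2 pairs may differ in kind. A floxed allele and Cd4cre are named for Itch KO and not for wild type, so the first pair cannot part Itch loss from these. The third pairing of the libraries, library labelled double KO over wild type against Itch KO over WWP2 KO, gave 0.61 and 0.36; both of its ratios also set an Itch-deficient label over an Itch-intact one, so it is no measure of chance for Itch.

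For WWP2, WWP2 KO over wild type was set against the library labelled double KO over Itch KO, and the correlation was 0.15 by either measure. There were 15 genes higher in both pairs, where independent lists would share 2.57, 2 lower in both, where 0.825 would be shared, and 5 in opposite directions. Among the shared genes Mid1 was 29.2-fold (23.6 to 36.5) and 19.4-fold (16.7 to 22.6) higher, Setbp1 4.26-fold and 6.89-fold (5.70 to 8.38), Pstpip2 13.4-fold and 4.98-fold (2.05 to 14.6), Cdc42bpb 3.68-fold and 2.31-fold (1.55 to 3.50) and Arrdc4 2.65-fold and 2.11-fold (1.57 to 2.86). The second ratio of Pstpip2 rests on few reads, with 19 in wild type, 6 in Itch KO, 251 in WWP2 KO and 32 in the library labelled double KO. Klk1b22 had 115 and 508 reads in the libraries with a WWP2-deficient label and 0 in the others. The 2 genes lower in both pairs were Fgfbp3 and, named after its values were seen, Tmco7, which had 490 reads in wild type, 381 in Itch KO, 231 in WWP2 KO and 135 in the library labelled double KO. Wwp2 itself was lower in the first pair and, at 0.795-fold (0.734 to 0.861), little lower in the second. Any direction assigned to WWP2 loss from the second pair therefore rests on a label that the counts put in doubt.

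**Figure D4:**
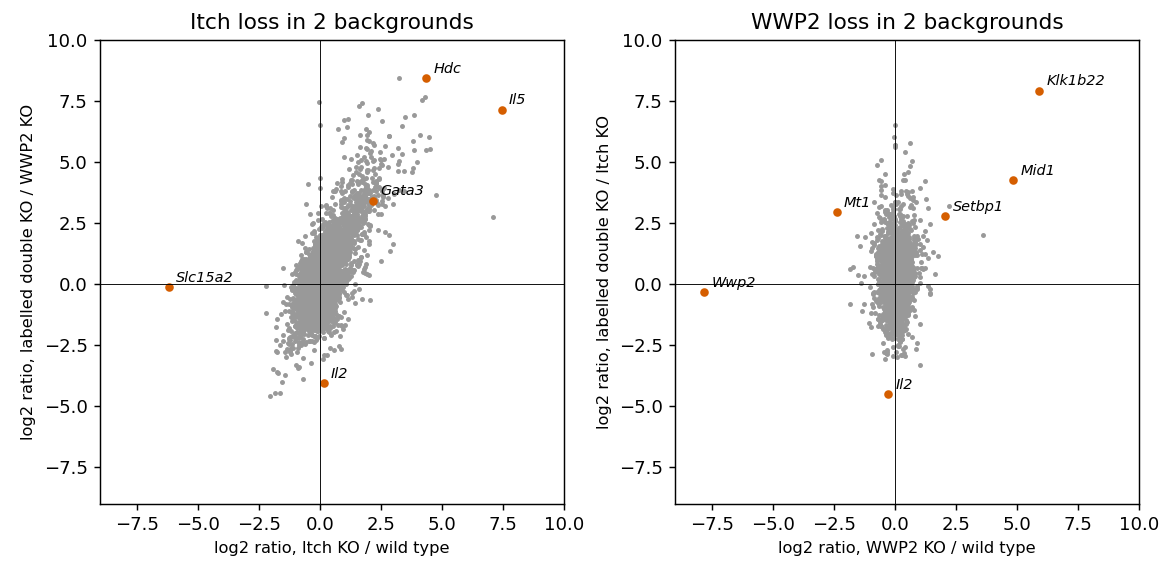
Log2 ratio of each of 9926 genes in pairs of libraries that share no library, for Itch (left, Itch KO over wild type on the x axis, the library labelled double KO over WWP2 KO on the y axis) and for WWP2 (right, WWP2 KO over wild type on the x axis, the library labelled double KO over Itch KO on the y axis). The left cloud follows a rising line (Pearson 0.70) and the right cloud is close to vertical (0.15), with Mid1 and Klk1b22 at its upper right.

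The single knockouts share the wild-type library, which by itself makes their differences correlate. Across genes, Itch KO over wild type and WWP2 KO over wild type had a correlation of 0.18 (Pearson). Simulated unchanged groups with a shared simulated control gave 0.50 at each dispersion, a value that the shared control sets by construction. The ratios of Itch KO spread more widely than those of WWP2 KO (standard deviations of 0.533 and 0.256), which lowers the observed correlation. No conclusion is drawn from 0.18 against 0.50. The covariance was 0.0242, against simulated values of 0.00954 with counting noise alone, 0.0304 at a dispersion of 0.01 and 0.0941 at 0.04. The observed covariance lies between the values for counting noise alone and for a dispersion of 0.01. The dispersion of these libraries is not known that closely, so whether the single knockouts share an effect beyond the shared control stays undecided. Both lists shared 13 genes higher, where independent lists would share 1.37, and 1 lower, while 7 genes went opposite ways. The shared library adds to the excess of genes that went the same way by an unmeasured amount.

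An additive model over all 4 libraries gave the only test between groups of libraries, 2 against 2 for each ligase, under the assumption that the effects add and with the label of the double KO taken as given. For Itch, 161 genes rose and 14 fell among 11197 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). Il5 rose by a fitted log2 change of 7.54 (adjusted p = 0.000518), Efna5 by 9.72 (0.00882), Cxcl3 by 5.13 (0.00932), Il13 by 4.22 (0.00932) and the protein S gene Pros1 by 4.44 (0.0114). Among those that fell were the transcriptional regulator gene Id3, with a log2 change of -2.07 (0.0429), the mitochondrial enzyme gene Pck2, with -1.90 (0.0433), Pik3ip1, with -1.80 (0.0433), and Bbc3, with -1.77 (0.0459). For each of these genes both libraries with an Itch-deficient label lay on the same side of both others. The fitted change of Efna5, with 0 reads in wild type, depends on the prior count.

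For WWP2, 3 genes rose and 0 fell in the same model. Mid1 rose by a log2 change of 4.57 (edgeR adjusted p = 0.00471), and Efna5, at 5.92, and Klk1b22, at 11.23, had adjusted p = 0.0455; Efna5 had 1 read in WWP2 KO and 1113 in the library labelled double KO, so its call comes from the latter. Klk1b22 had 0 reads in both libraries with a WWP2-intact label, so its fitted change is set by the prior count and is no measured fold. With DESeq2 neither of these 2 genes passed, and with limma-voom Efna5 had an adjusted p of 0.262 and Klk1b22 of 0.00550. At an unadjusted p below 0.05 there were 404 genes for WWP2 and 1652 for Itch, by the edgeR test. For WWP2 that is less than a share of 0.05 of the 11197 genes tested, the share expected with no effect and a residual of noise alone. The residual here also holds departures from additivity, which lowers the count. A count below that share therefore does not show that WWP2 loss had no effect. For WWP2 the counts were 8 higher and 0 lower by DESeq2 and 2 and 0 by limma-voom. At an unadjusted p below 0.05 these tests had 391 and 704 genes, of which only the limma-voom count exceeds that share. Wwp2 itself was not called (log2 change -3.14, edgeR adjusted p = 0.874), since its reads in the library labelled double KO went into the residual. The count for Itch moved with the scaling, to 19 higher and 0 lower with DESeq2 size factors in edgeR, and with the tool, to 513 and 102 with DESeq2's Wald test. The common dispersion of 0.0536 takes in any departure from additivity.

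Markers of other cells were measured beside these groups. In Itch KO, all 4 B cell list genes past the filter, Cd74, H2-Aa, H2-Ab1 and H2-Eb1, were higher, at log2 ratios of 1.76 to 3.01, and they also serve antigen presentation outside B cells. Cd79a, a B cell gene below the filter and chosen after its values were seen, had 34, 16, 39 and 14 reads, in the order wild type, Itch KO, WWP2 KO and labelled double KO. Of the NK and ILC1 markers, 3 of 6 were higher and 1 lower in Itch KO, with Gzma at 4.19 and Klrb1c at -1.21. In the library labelled double KO 2 were higher, Gzma at 7.22 and Gzmb at 6.26, and 3 lower, with Klrb1c at -2.77 and Xcl1 at -3.02, so that the median of -0.98 and the mean of 0.96 differ in sign. CD8 T cell markers were higher in 3 of 6 cases in Itch KO (Nkg7 at 2.03) and in 1 of 6 in the library labelled double KO, where 2 were lower (Klrd1 at -2.26). Of 4 basophil and mast cell markers past the filter, Hdc, Il4 and Csf1 were higher and Kit lower in both of these libraries; T cells also make Il4 and Csf1.

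Monocyte and macrophage markers were higher in 1 of 6 cases in Itch KO (Mpeg1, 2.04), and in the library labelled double KO 2 were higher (Hmox1 at 2.68 and Cd68 at 2.62) and 2 lower (Mpeg1 at -1.04 and Apoe at -1.08). Dendritic cell markers were higher in 1 of 6 cases in each (Xcr1, 1.04 and 2.43). Plasma cell markers were higher in 2 of 3 cases in Itch KO and 3 of 3 in the library labelled double KO, with Sdc1 at 1.69 and 4.18 and Prdm1, which effector T cells also express, at 1.95 and 3.88. The stromal list had 2 members past the filter, of which Col1a1 was higher at 2.95 and 6.05. The erythroid list had 2, of which Car2 was lower in the library labelled double KO alone, and the neutrophil list had 1, Cxcr2, which did not pass. In WWP2 KO, 0 markers of the lists of other cells passed the rule, but CD8 T cell markers had a median of -0.52 (0 of 10000 matched lists at or below it), NK and ILC1 markers -0.44 (2 of 10000) and basophil and mast cell markers 0.31 (15 of 10000 at or above it).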

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

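The tests of explanations in this part were chosen only after the result was seen. Among 74 named genes, those listed here had ratios on opposite sides of 1, by their counting intervals, when the other ligase was intact and when it was labelled lost. Of these genes only Mt1, Mt2 and Rpph1 passed the 2-fold rule in both backgrounds. Each side of each comparison is 1 library, and the difference was not tested. The values are departures from additivity on the log2 scale, the difference between the effects in the 2 backgrounds. Since the library labelled double KO held Wwp2 reads against its label, the direction in the second background rests on a doubtful genotype.

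For Itch loss the departure was -4.24 for Il2 (effects of 0.17 and -4.07), -2.25 for Csf2 (1.46 and -0.79), -1.79 for Mctp1 (1.18 and -0.62), -1.22 for Tbx21 (0.20 and -1.02), -1.18 for Foxp3 (0.74 and -0.44) and -1.13 for Ifng (0.58 and -0.54). It was 1.02 for Phlda3 (-0.45 and 0.57) and 0.27 for Itch itself (-0.12 and 0.14), whose gene-level reads do not report the deletion.

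For WWP2 loss the departure was -3.19 for Adamts6 (effects of 0.26 and -2.93), -2.87 for Arhgap29 (0.71 and -2.16), -2.55 for Amigo2 (0.19 and -2.36), -2.30 for Ttc28 (0.41 and -1.90), -1.85 for Msi2 (1.45 and -0.39), -1.18 for Foxp3 (0.35 and -0.83) and -1.11 for Il13 (0.91 and -0.20). It was 5.32 for Mt1 (-2.38 and 2.93), which had 40, 88, 6 and 735 reads in the order wild type, Itch KO, WWP2 KO and labelled double KO. It was 3.54 for Mt2 (-1.57 and 1.96), 2.98 for Rpph1 (-1.42 and 1.57), 2.48 for Il3 (-1.84 and 0.63), 2.41 for Pttg1 (-1.73 and 0.68) and 2.10 for Eps8l1 (-0.36 and 1.74). The metallothioneins respond to metal in the medium and share sequence, and Rpph1 lacks a poly(A) tail, so its level also depends on mRNA enrichment.

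A pattern behind many of these values is that the library labelled double KO stands apart, at least 2-fold above the other 3 for 749 genes and below them for 336. A stimulation of that culture weaker for all induced genes alike would bring immediate early genes near the fall of Tnf (-2.09). Their median log2 ratio to wild type was 0.51, more than their standard deviation of 0.93 away. This gap cannot decide against such a stimulation, since Tnf was taken as the yardstick after its fall was seen. No unstimulated library was at hand, so whether the immediate early genes were still induced at harvest is not known. Against Itch KO their median was 0.07, with 1 gene higher and 5 lower. A weaker stimulation, alike for all induced genes or unequal, stays open, since a list median cannot decide it. Basophils or mast cells in the preparation as the source of Hdc are argued against: 7 of their markers summed to 17 reads, 0.152% of the Hdc count. Another length of stimulation before harvest stays open, since ribosome biogenesis genes (median -0.91) and immediate early genes part from each other and no time course was at hand. The joint loss of both ligases, which the design names, and differences between single mice or cultures also stay open as untested.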

How the results depend on the processing

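Scaling without the library labelled double KO was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the samples carry no pairing, and with 1 library per genotype none can be left out. Counts are given as higher then lower unless said otherwise, and double means the library labelled double KO.

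With no low filter, Itch KO against wild type had 183 genes lower, WWP2 KO against wild type had 117 and 56, and the double had 1924 higher than wild type, 1421 higher than Itch KO and 1780 higher than WWP2 KO. Above and below all others lay 6 and 22 genes for wild type, 52 and 17 for Itch KO, 8 and 17 for WWP2 KO. Correlations fell to 0.53 for the Itch pairing and 0.46 for the third pairing, and stood at 0.28 for the single knockouts. In both pairs, 93 genes were lower for Itch, and 37 and 8 for WWP2. Departures were 1866 above and 1293 below. More genes were counted there by construction.

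At a mean of at least 10 CPM the counts were 233 and 45 for Itch KO and 6 and 7 for WWP2 KO, and the double had 666 higher than wild type, 452 higher than Itch KO, and 625 and 392 against WWP2 KO. Below all others were 2 genes for wild type; Itch KO had 8 above and 4 below, WWP2 KO had 4 below, and the double had 372 above. In both pairs were 198 and 36 for Itch and 4 and 1 for WWP2. Departures were 428 and 334. Fewer genes were counted by construction.

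With the stricter counting interval, 7 genes lay below all others in wild type, 5 in Itch KO and 6 in WWP2 KO, and 1 was lower in both WWP2 pairs. At a ratio of 1.5 the counts were 872 and 436 for Itch KO, 118 and 75 for WWP2 KO, and for the double 2033 and 1740 against wild type, 1933 and 1435 against Itch KO, 1950 and 1665 against WWP2 KO. Apart from all others were 11 and 44 for wild type, 70 and 60 for Itch KO, 17 and 33 for WWP2 KO, 1416 and 1046 for the double. In both pairs were 705 and 245 for Itch and 59 and 21 for WWP2. Departures were 1871 and 1451.

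Spearman correlation was 0.45 for the Itch pairing and 0.36 for the third. In the additive model Itch loss had 513 and 102 genes with DESeq2, 397 and 56 with limma-voom, 19 and 0 with DESeq2 size factors in edgeR, and 466 and 76 with no low filter. WWP2 loss had 8 higher with DESeq2 and 1 with DESeq2 size factors. The cause was not tested.

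For the double against wild type, the mean had the opposite sign to a median that lay outside the middle 95% of matched lists for TFH (0.0141), cytokines and chemokines (0.68) and NK and ILC1 markers (0.96). Medians inside that range also differed in sign from their means, for stress response (-0.43), heat shock (0.17), TGF-beta (0.12) and dendritic (0.19) and CD8 T cell markers (-0.08). Of the other alternatives to list medians, 410 values stayed within their tolerance and 43 moved, and 888 log2 ratios of named genes stayed. Plain totals, a prior count of 0.5, thinned counts and the removal of receptor segments, sex-linked genes and other-cell markers left each count of the size rule within 1.5 times and each correlation within 0.1, and so did scaling without the library labelled double KO for the 4 results it covered. The 3 results that moved with DESeq2 size factors were those of the additive model above. Depth limits genes near 2 CPM, where a few reads decide a call.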

Other observations

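The tests of explanations in this part were chosen only after the result was seen. In the list of the unfolded protein and integrated stress response, 10 of 28 genes were lower and 4 higher in the library labelled double KO than in wild type; the lowest were the cystine transporter gene Slc7a11, at a log2 ratio of -4.59, and Trib3, at -2.95, and the highest Atf6, at 1.60, and Sdf2l1, at 1.06. The list median was 0.02 (percentile 87.1) and its mean -0.43 (percentile 0.380). The direction in the library labelled double KO belongs to a library whose Wwp2 reads put its label in doubt.

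Interferon response genes went both ways, 6 of 34 higher and 5 lower in that library (median -0.20, percentile 12.9), 2 higher and 3 lower in Itch KO (-0.21, percentile 0.0600) and 0 either way in WWP2 KO (0.18, percentile 100). In the library labelled double KO they spread from Ifi204 at 4.67 and Mx1 at 1.60 to Ifit1 at -2.43 and Ifit3 at -3.40. Negative regulators of the T cell receptor were higher in 4 of 27 cases and lower in 3, with Rnf128, the anergy ligase GRAIL, at 2.72, Dok2 at 2.62, Cd5 at -1.24 and Spry1 at -2.14. In Itch KO Rnf128 was higher at 1.13 and Ptpn6 lower at -1.03. JAK STAT genes were higher in 6 of 29 cases in Itch KO, led by Socs2 at 1.90 and Socs3 at 1.85. Of the NEDD4 family and its adaptors, 4 of 14 were higher in the library labelled double KO, with Arrdc4 at 1.85 and Nedd4 at 1.66, and 0 in Itch KO. Glycolysis genes were higher in 3 of 20 cases and lower in 1, from the lactate exporter gene Slc16a3 at 2.16 to Pdk1 at -1.52. The NFAT and calcium pathway had 4 of 19 higher and 0 lower, with Itpr1 at 1.89 and Nfatc2 at 1.73. Apoptosis regulators were higher in 6 of 25 cases and lower in 1, with Pmaip1 at 2.39, Bad at 2.22 and Bbc3 at -2.20. Oxidative phosphorylation genes (37) and ribosomal protein genes (42) had 0 past the size rule in either direction. The agouti gene, a neighbour of Itch chosen after its values were seen, had 28 reads in the library labelled double KO and 0 in the others.

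The Wwp2 reads in the library labelled double KO were weighed first. A swap of the labels of 2 libraries is argued against, since only 1 library of the 4, WWP2 KO with 4 reads, was nearly without Wwp2, where the labels need 2. RNA mixed in from cells like those of the wild-type or Itch KO library would need a share of at least 0.717. Against this, 39 of 7516 genes lay below 35.9% of their level in wild type and in Itch KO, by their upper bounds. A bound of 50 such genes, set first, was not reached and was lowered after the count was seen, because such a mixture allows none. Cells mixed in before culture, which answered to it, stay open, and so do cells with more Wwp2, which would need a smaller share. The Wwp2 allele of the WWP2 KO library is argued against as a keeper of gene-level reads, since Wwp2 stood at 0.297% of wild type there. A wrong genotype label of this library alone and a second, different Wwp2 allele that keeps such reads cannot be told apart by the level of 77.7% of wild type, since counts per exon were not used here.

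The 17 genes that differ the same way in both libraries labelled WWP2-deficient, each set against the library of the same Itch label, were weighed as well. Independent lists would share 3.40. For the 16 genes other than Tmco7, passenger DNA beside the Wwp2 gene is argued against. Of them 0 were among the 50 measured genes nearest on each side, a neighbourhood in which 65 genes passed the low filter. Tmco7 itself is the 15th measured gene from Wwp2, and passenger DNA or a local effect could account for it. The Wwp2 level in the library labelled double KO, 77.7% of wild type, argues against absence of Wwp2 transcript as the cause in both libraries. The exception would be Wwp2 reads from mixed-in cells of the kinds left open above. A genetic background shared by the mice away from Wwp2 stays open, because the genes lie on 11 chromosomes and reads that show sequence variants were not used here. Loss of WWP2 protein, named by the design, stays open as untested.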
